A study of Mus musculus with 24 samples.

How the data were processed

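The series holds chromatin immunoprecipitation with sequencing (ChIP-seq) of the histone variant H2AX and of its phosphorylated form γH2AX, which marks chromatin around DNA breaks, together with input DNA. The cells were female mouse cells of a C57BL6/CAST hybrid background that the labels call TTF, either wild type (WT) or lacking SIRT7 (KO), a deacylase of chromatin. A further set comprised KO clones c22 and c9, the same clones carrying SIRT7-WT, and clones named HY (c5 and c7), an abbreviation that the labels leave unexplained. Per the labels' protocols, all 24 samples received 5 Gy of X-rays with 30 minutes of recovery, chromatin was sheared to 300 to 500 bp, and the immunoprecipitations used antibodies against H2AX or γH2AX. The samples form 12 groups of 2.

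The authors deposited 2 tables of raw read counts per 1 Mb bin of the mouse genome, build mm10 per the submitters' processing notes, with no scaling of the counts. Those notes name FastQC 0.11.3, Trimmomatic 0.36, Bowtie2 2.2.9, SAMtools 0.1.19, deepTools 2.4.2 and MACS2 2.2.7.1. Their settings, the treatment of duplicate reads and the way reads were assigned to bins or to parental genomes are not given in the sources used here. The first table covers WT and KO cells, and the second the clones and WT cells again. Both also carry counts per parental genome (genome1, genome2 and unassigned), as deposited by the authors.

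Columns were matched to samples by name. The 12 total columns of the first table name the antibody and genotype and end in NT or Xray, whereas every label states X-ray treatment and numbers the samples. They were therefore matched to their groups only, as 2 replicates each, and are called here the NT-named and Xray-named libraries. The 12 clone columns were matched to their groups by clone type and carry a replicate number, but which number is which clone stayed open. WT columns of the second table matched WT replicates 1 and 2 by title. Of the 144 columns of values, 48 were used and 96 were not. The unused ones were 72 columns of parental genomes whose library matched a group only and 24 input columns of the second table. The latter are named for the clones, for which no labelled input sample exists. WT replicate 2 of the second table was identical to the NT-named WT library in 2645 of 2645 bins in each assay, and WT replicate 1 was not, so 3 distinct WT libraries exist per assay for 2 labelled samples. The 2 tables were never joined in a fit. The labels name 2 clones per clone group. Nothing in them says that WT or KO replicates came from separate cultures, so p-values there measure only the spread between these samples, which may be technical.

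Bins of chromosomes 1 to 19 and X with a mean count of at least 100 over the 12 libraries of a fit were tested, 2582 of 2645, of which 168 lay on X. Libraries held 170013624 to 268180310 reads in the first table as deposited by the authors (median 55282 to 88979 per bin) and 70349148 to 155364952 in the clones (24900 to 54669 per bin). Counting error is therefore small against the spread between libraries, whose biological coefficient of variation was 3.23% in the first table and 11.4% in the clones. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM factors, a coefficient per group, all 12 libraries of a table sharing the estimate of spread, two-sided, with Benjamini-Hochberg adjustment over the bins and a threshold of 0.05. An adjusted p printed without a tool comes from this test. The shared estimate hides that the assays differed in spread. Over bins, the log2 difference of NT-named and Xray-named libraries had an SD of 0.11 (KO) and 0.101 (WT) in γH2AX. It was 0.0239 and 0.0463 in H2AX, and 0.0251 and 0.0236 in input. P-values of γH2AX may therefore be too small, and differences between H2AX and input may be missed. Differences of differences (γH2AX relative to H2AX, for example) were contrasts in the same fit. Chromosome-level values came from the same test on counts summed per chromosome, scaled to the autosomal total, adjusted over the 20 chromosomes. With 2 libraries against 2, an exact permutation test cannot fall below 0.333, so none is reported. CPM were computed here from the deposited counts with edgeR's cpm function, on library sizes adjusted by TMM.

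In simulated counts with 50 bins changed at each of 4 sizes, the KO against WT comparison of γH2AX recovered 46% of bins changed 1.1-fold and 100% of those changed 1.25-fold or more, with 5 unchanged bins called (2.81% of calls). The comparison of KO clones with and without SIRT7-WT recovered 0% at 1.1-fold, 12% at 1.25-fold, 68% at 1.5-fold and 100% at 2-fold, with 1 unchanged bin called (1.1%). The simulation drew every library independently, with the same spread for all assays. In the first table γH2AX spread more, and its KO and WT libraries of like name deviated together (r = 0.959). These rates may therefore not hold for the γH2AX data.

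Bins are named by position and by genes of 19 lists. These were the X inactivation centre, X structure loci, escape genes, DNA damage response, p53 targets, fibroblast genes, long fragile-site genes, imprinted clusters, Hox clusters, replication-dependent histone genes, all X bins, X bins proximal and distal to Dxz4 (4933407K13Rik), chromosomes with ribosomal DNA arrays (12, 15, 16, 18 and 19), centromere-proximal and distal bins (the first and last 5 tested bins of each autosome), olfactory receptor bins (at least 5 such genes), gene-rich bins (the 241 autosomal bins with most protein-coding genes) and gene-poor bins (no protein-coding gene start). All 77 listed symbols matched the RefSeq gene table of GRCm38.p6, the assembly also called mm10. The lists, the comparisons, the tests, the rule for named bins and the alternatives were set before the data were examined, apart from those said to be added. Under that rule the text names, for each comparison of bins, the 10 largest increases and 10 largest decreases with adjusted p below 0.05 whose libraries do not overlap in CPM (for differences of differences, adjusted p alone), at most 6 of each where neighbouring bins form a run. It also names every bin with a gene of the first 4 lists, the X chromosome, each autosome that passed, and, where no bin passed, the 3 with the smallest p. Lists were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 19 lists of a comparison, and again with an estimated correlation.

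Agreement between tables was measured by correlation over bins, which are not independent replicates, with a permutation p from 1000 circular shifts along the genome. Alternatives were DESeq2 size factors, the autosomal total as scaling, DESeq2's Wald test (DESeq2 1.42.0), no count filter, leaving out bins with unusual input (over 3 median absolute deviations), fitting the compared groups alone, leaving out each library, a replicate block for the clones, and the difference against input. Clones with and without SIRT7-WT are the same cell lines per the labels, and their libraries of like number deviated together over bins (r = 0.854 in γH2AX and 0.936 in H2AX), so the replicate number pairs them. Added after the data were seen were comparisons relative to input, HY clones relative to H2AX, a block by column name, fits to NT-named or Xray-named γH2AX libraries alone, and the parental-genome ratio in WT. Fits to γH2AX libraries of like name have 1 per genotype and so no replicate check, and their p-values are left out of the text and of ranges. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and plots.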

Results

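The series title places the work in the study of SIRT7, dosage compensation and the female X chromosome, and its design profiles H2AX and γH2AX in WT and SIRT7-KO hybrid female cells. The data analysed here were read counts per 1 Mb bin from 24 labelled samples in 12 groups of 2: γH2AX, H2AX and input in WT and KO cells, and γH2AX and H2AX in KO clones, in KO clones carrying SIRT7-WT, and in HY clones. The median bin held 55282 to 88979 reads in the WT and KO libraries and 24900 to 54669 in the clone libraries. Every label states X-ray treatment, yet the 2 columns of each WT and KO group are named NT and Xray, so the libraries are referred to by those names and the 2 were treated as replicates, as the labels have them.

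The targeted gene was examined first. Sirt7 (chromosome 11, 120618371 to 120625014, mm10) lies within the bin 120000001 to 121000000, which also holds many other genes, so a deletion of the gene alone would not be resolved. In γH2AX the bin held 258 and 282 CPM in the KO libraries against 522 and 572 in WT. In H2AX it held 278 and 277 CPM in KO against 534 and 558 in WT, and in input 218 and 218 against 415 and 406. The bin fell by 1.02 on the log2 scale in γH2AX (SE 0.0498, adjusted p = 2.11e-06), by 0.98 in H2AX (2.33e-06) and by 0.91 in input (1.77e-06). The reduction covered the last 4 bins of chromosome 11 (118000001 to 122000000), which hold Timp2, Cbx2, Cbx8, Rptor and Foxk2 among others. All 4 fell in each assay, with mean log2 changes of -1.07 in γH2AX, -0.97 in H2AX and -0.92 in input.

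The first question was how loss of SIRT7 altered γH2AX along the genome. KO cells carried more reads from the X chromosome than WT cells, in γH2AX, in H2AX and in input alike. X reads amounted to 5.49% ± 0.0064 of autosomal reads in γH2AX of KO cells (SD, n = 2) and to 4.78% ± 0.05 in WT (n = 2). In H2AX the shares were 5.5% ± 0.013 and 4.83% ± 0.041, and in input 5.67% ± 0.028 and 5.11% ± 0.0014 (n = 2 each). The X rose by 0.20 on the log2 scale in γH2AX (SE 0.00965, adjusted p = 1.23e-07), 0.19 in H2AX (2.04e-07) and 0.15 in input (1.26e-06).

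**Figure D1:**
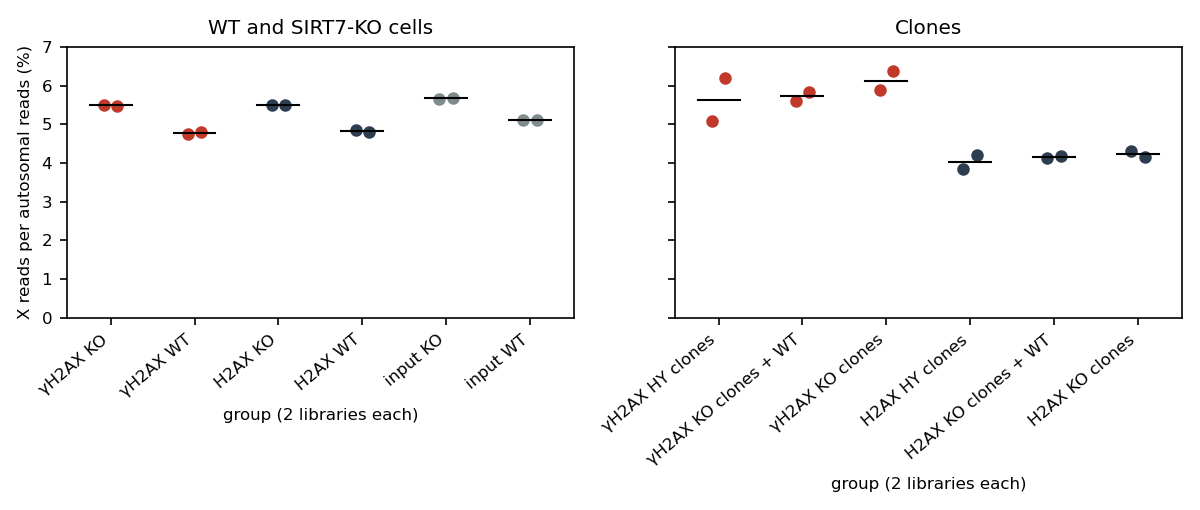
Reads on the X chromosome as a percentage of autosomal reads (vertical axis) for each library (points) and group mean (lines), by assay and group, with WT and KO cells on the left and clones on the right. The KO libraries lie above the WT libraries in γH2AX (means 5.49% and 4.78%), in H2AX and in input.

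Several autosomes also differed between KO and WT, again with like values in the 3 assays. Chromosome 10 rose most in γH2AX, by 0.37 (SE 0.0115, adjusted p = 9.29e-09), against 0.39 in H2AX and 0.38 in input. Chromosomes 16 (0.19), 15 (0.16), 8 (0.15), 11 (0.13), 9 (0.073) and 18 (0.062) also rose in γH2AX, and each rose in H2AX and input as well. Chromosome 6 fell most, by 0.27 in γH2AX (SE 0.0102, adjusted p = 3.3e-08), by 0.27 in H2AX and by 0.28 in input. Further decreases in γH2AX were those of chromosomes 5 (-0.23), 3 (-0.21), 7 (-0.094), 1 (-0.082), 4 (-0.082), 12 (-0.064), 13 (-0.046) and 14 (-0.038), and these passed in H2AX and input too, except chromosome 14. Chromosome 17 passed in H2AX (-0.20, adjusted p = 0.0229) and input (-0.20, adjusted p = 0.0271) but not in γH2AX (-0.022, adjusted p = 0.802). Its γH2AX value includes the bin 39000001 to 40000000, which held a mean of 12300 CPM in KO and 7530 in WT. In H2AX that bin held 441 and 509 CPM, and in input 580 and 586. Without that bin no chromosome value is given here, so a difference between assays over the whole chromosome is not shown.

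**Figure D2:**
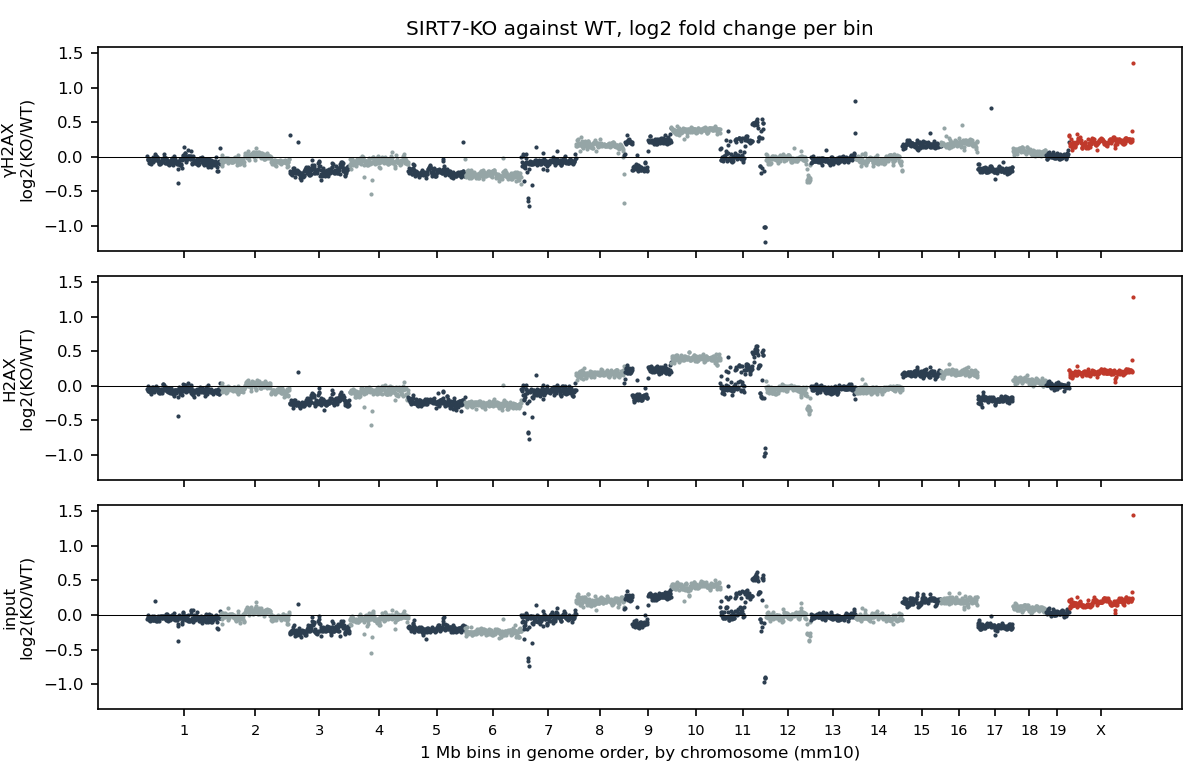
Log2 change of KO against WT (vertical axes) for each tested 1 Mb bin in genome order (horizontal axis, chromosomes 1 to 19 and X, X in red), in γH2AX, H2AX and input from top to bottom. Whole chromosomes and segments shift together and alike in the 3 assays, with the X raised, the end of chromosome 11 lowered by about 1 and the bin at the end of X the highest point (1.36 in γH2AX).

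Of 2582 bins, 777 were higher and 776 lower in γH2AX of KO cells, 791 and 843 in H2AX, and 828 and 656 in input. On the X, 167, 167 and 166 of 168 bins were higher. The bin with the largest increase was X 170000001 to 171000000, at the end of the chromosome, which holds Asmt, a gene of the pseudoautosomal region. It rose by 1.36 in γH2AX (SE 0.0509, adjusted p = 4.01e-07), from 39.6 ± 2.27 CPM in WT to 101 ± 0.415 in KO (SD, n = 2 each), and by 1.29 in H2AX and 1.45 in input. Most of the other large increases lay together on chromosome 11, among them 98000001 to 99000000, with the receptor kinase gene Erbb2 and the topoisomerase gene Top2a (0.55 in γH2AX, 0.58 in H2AX, 0.62 in input), 113000001 to 114000000 with Sdk2 (0.54), 97000001 to 98000000 with Tbx21 and Kpnb1 (0.51) and 96000001 to 97000000 with the Hoxb cluster (0.50). Over the whole stretch from 91000001 to 118000000, chosen after its values were seen, the mean was 0.31 in γH2AX, 0.30 in H2AX and 0.34 in input, and 26, 24 and 23 of 27 bins passed.

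Decreases outside chromosome 11 included bins filled with gene families. The 3 bins from 20000001 to 23000000 of chromosome 7, filled with Vmn1r vomeronasal receptor genes, had mean log2 changes of -0.65 in γH2AX, -0.71 in H2AX and -0.68 in input. The bin 60000001 to 61000000 of chromosome 4, with the major urinary protein genes (Mup), fell by 0.54, 0.57 and 0.56, and 32000001 to 33000000 of chromosome 7, with secretoglobin genes such as Scgb1b10, by 0.41 in γH2AX (SE 0.0462). In H2AX, 48000001 to 49000000 of chromosome 10 was among the largest increases (0.49), and 85000001 to 86000000 of chromosome 1, with Sp100, Sp110 and Sp140, among the largest decreases (-0.44). Members of such families are near-identical copies, so their reads may be shared between bins. The last bin of chromosome 13 (120000001 to 120421639, with Tcstv3 and AF067061) rose by 0.81 in γH2AX (SE 0.100, adjusted p = 0.000104) with 0.012 in input (adjusted p = 0.937). The last bin of chromosome 8 (129000001 to 129401213, with Ccdc7b) fell by 0.66 in γH2AX (adjusted p = 0.00016) with 0.12 in input (adjusted p = 0.296). Fitting the compared groups alone gave 919 called bins in γH2AX instead of 1553.

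Loci of X inactivation moved with their chromosome. The bin with Xist, the RNA that coats the inactive X, and with Tsix, Jpx, Ftx and Rlim (X 103000001 to 104000000) rose by 0.20 in γH2AX (SE 0.0361, adjusted p = 0.00102), 0.19 in H2AX and 0.23 in input. Firre (0.14) and 4933407K13Rik, the Dxz4 locus that separates the megadomains of the inactive X (0.18), rose too. All 6 bins of genes that escape X inactivation rose in γH2AX: Mid1 (0.37), Kdm5c (0.27), Pbdc1 (0.20), Eif2s3x (0.18), Ddx3x (0.16) and Kdm6a (0.15). Among bins of DNA damage response genes, Brca1 (0.41 in γH2AX, 0.49 in input), Rnf168 (0.19) and Prkdc (0.14) rose. Sirt7, Atm (-0.17), H2ax itself (-0.19), Mdc1 (-0.20) and Rnf8 (-0.20) fell, and Trp53bp1 did not pass (-0.014, adjusted p = 0.785). The call of H2ax was lost without the NT-named γH2AX KO library (-0.097, adjusted p = 0.179) or the Xray-named γH2AX WT library (-0.090, adjusted p = 0.207), and that of Rnf8 without the latter (-0.14, adjusted p = 0.0575).

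Over the lists, γH2AX of KO against WT was higher in 1 of 1 bin of the X inactivation centre, 2 of 2 X structure loci and 6 of 6 escape genes. The counts were the same when adjusted over the list alone (1, 2 and 6). Of 9 DNA damage response bins 3 rose and 5 fell (8 adjusted over the list alone), and of 10 p53 target bins 1 rose and 3 fell (4). Of 9 fibroblast gene bins 3 rose and 3 fell (6), of 27 bins of long fragile-site genes 5 rose and 8 fell (13), and of 14 imprinted bins 2 rose and 7 fell (9). Of 4 Hox bins 2 rose and 1 fell (3), and both bins of replication-dependent histone genes fell (2). Of X bins, 71 of 72 proximal and 95 of 95 distal to Dxz4 rose (72 and 95 adjusted over the list alone, and 168 of all 168). On chromosomes with ribosomal DNA arrays 221 of 462 bins rose and 15 fell (234). Centromere-proximal bins had 25 higher and 27 lower of 95 (50), distal bins 25 and 35 of 95 (60), olfactory receptor bins 13 and 13 of 54 (26), gene-rich bins 67 and 69 of 241 (135) and gene-poor bins 76 and 74 of 287 (148). Camera placed 5 lists above the remaining bins: all X bins (adjusted p = 1e-32, and adjusted p = 0.0871 with an estimated correlation), X bins proximal (2.04e-18, 0.0871 with the estimate) and distal to Dxz4 (1.64e-24, 0.13 with the estimate), escape genes (0.00414, 0.377 with the estimate) and chromosomes with ribosomal DNA arrays (1.03e-09, 0.0133 with the estimate). The last of these also held with an estimated correlation in H2AX (adjusted p = 0.0154) and input (adjusted p = 0.01), and no other list call in any comparison did. Its chromosomes did not move together in γH2AX. As wholes, chromosomes 16 (0.19), 15 (0.16) and 18 (0.062) rose, 12 fell (-0.064) and 19 did not pass (-0.0011). The list takes whole chromosomes, so the call is not particular to ribosomal DNA.

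Next it was asked whether γH2AX changed beyond H2AX or beyond input DNA. Most of the difference was shared, and few bins differed between assays in these fits, which do not use the column names. An added fit that does use them called many more bins relative to input, for γH2AX and for H2AX, and is in the closing section. Over bins, the KO against WT change of γH2AX correlated with that of input at r = 0.96 and with that of H2AX at r = 0.952. Relative to H2AX, the X changed by 0.013 (SE 0.0136, adjusted p = 0.988) and the Xist bin by 0.0067 (SE 0.051, adjusted p = 0.997). Every other bin of the X inactivation centre, X structure, escape and DNA damage response lists had an adjusted p of 0.997 or 0.998 relative to H2AX and of 0.937 to 0.973 relative to input. Relative to input, the X changed by 0.052 (SE 0.0136, adjusted p = 0.105, range over alternatives 0.021 to 0.518). That value passed without the Xray-named γH2AX WT library (0.063, adjusted p = 0.021). It was 0.064 with NT-named and 0.040 with Xray-named γH2AX libraries alone, which have no replicate check. No autosome passed in either comparison.

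**Figure D3:**
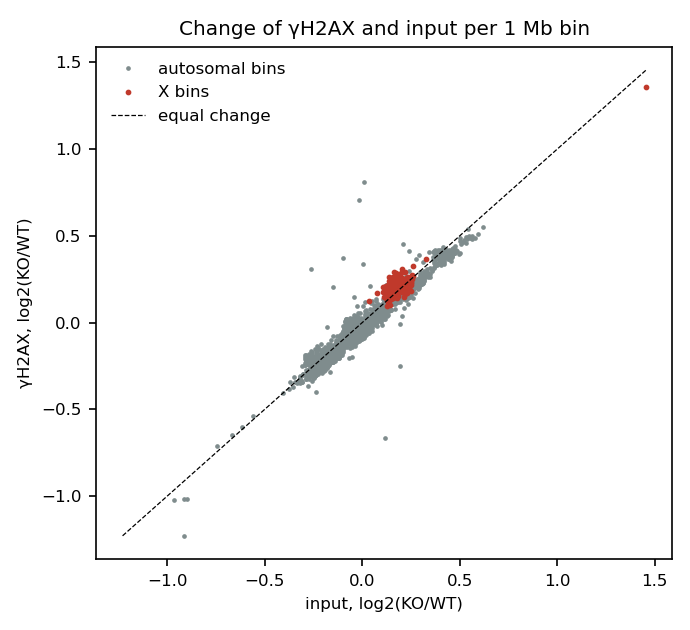
Log2 change of KO against WT in γH2AX (vertical axis) against that in input (horizontal axis), with a point per 1 Mb bin, autosomal bins in grey, X bins in red and equal change as a dashed line. The points follow the line over its whole length (r = 0.96), and few lie away from it.

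Of 2582 bins, 4 passed relative to H2AX, 1 higher and 3 lower, and all lay among the last 2 bins of a chromosome. Most chromosome ends did not share this. Outside chromosomes 8, 11 and 13 no end bin passed, and the last bins changed by -0.19 (chromosome 6) to 0.24 (chromosome 19). The last bin of chromosome 13 rose by 1.00 (SE 0.142, adjusted p = 0.0329), with γH2AX of 264 and 205 CPM in KO and 141 and 127 in WT. The last bins of chromosome 8 fell by 0.96 (129000001 to 129401213, SE 0.126, adjusted p = 0.0328) and by 0.49 (128000001 to 129000000, with the receptor genes Nrp1 and Itgb1, SE 0.0698, adjusted p = 0.0329). The last bin of chromosome 11 (121000001 to 122000000) fell by 0.32 (SE 0.0305, adjusted p = 0.00396), with γH2AX of 258 and 260 CPM in KO and 609 and 604 in WT. It was also the only bin of 2582 to pass relative to input in this fit, at -0.32 (SE 0.0305, adjusted p = 0.00447). With the compared groups alone all of these calls were lost (adjusted p = 0.112 for the chromosome 11 bin, 0.257 for the other 3, and 0.123 relative to input). Leaving out a library of H2AX left 0 of the 4 calls without the NT-named KO, the Xray-named KO or the Xray-named WT library, and 1 without the NT-named WT library. The adjusted p of the chromosome 11 bin was then 0.0533, 0.0646 and 0.0548 in the first 3 cases (range over alternatives 2.28e-32 to 0.112), and the highest for the other bins was 0.448, 0.416 and 0.475, each without the Xray-named WT library. The chromosome 13 bin also lost its call without the Xray-named γH2AX WT library (0.90, adjusted p = 0.0856), and 128000001 to 129000000 of chromosome 8 without the Xray-named γH2AX KO library (-0.48, adjusted p = 0.087). The call relative to input was lost without the NT-named input KO (adjusted p = 0.0683), Xray-named input KO (0.0725) or Xray-named input WT library (0.157), within 9.61e-25 to 0.157 over alternatives. Leaving out a γH2AX library instead gave 4 bins relative to input (without the NT-named KO library) or 3 (without any other).

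At an unadjusted p under 0.05 there were 70 bins relative to H2AX and 29 relative to input, and DESeq2 called 16 and 6. The comparisons relative to input were added. In the fit that does not use the column names, H2AX relative to input changed in 0 bins by edgeR's quasi-likelihood test (128 at an unadjusted p under 0.05, 12 by DESeq2), and the X by 0.039 (adjusted p = 0.414), with an adjusted p of 1 in every bin of the X and DNA damage response lists. The 3 bins with the smallest p, none of which passed, were 97000001 to 98000000 of chromosome 5 with Antxr2 (-0.21, adjusted p = 0.0688), 24000001 to 25000000 of chromosome 1 with the collagen genes Col9a1 and Col19a1 (-0.25, adjusted p = 0.0688) and 95000001 to 96000000 of chromosome 12 with Flrt2 (-0.31, adjusted p = 0.116). Camera called 4 lists for γH2AX relative to H2AX. All X bins were higher (median 0.023, adjusted p = 0.00641), as were X bins distal to Dxz4 (0.028, adjusted p = 0.00184) and gene-poor bins (0.029, adjusted p = 0.00672), and gene-rich bins were lower (-0.021, adjusted p = 0.00641). None of the 4 held, with adjusted p = 0.859 for each with an estimated correlation. Relative to input 7 lists were called for γH2AX, the X bins among them (median 0.030, adjusted p = 4.53e-33, and adjusted p = 0.112 with an estimated correlation), and 4 for H2AX, and none of these held either (lowest adjusted p = 0.104 and 0.282 with the estimate).

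To describe where γH2AX lay, it was compared with input within each genotype. H2AX was not tested against input in this way, so a difference given below may be shared with H2AX. In WT cells γH2AX exceeded input in gene-rich bins and fell below it in gene-poor bins and on the X, and KO cells had the same directions. The camera calls of gene-rich and gene-poor bins were lost with an estimated correlation (adjusted p = 0.536 in WT and 0.746 in KO for both lists). In WT 893 bins were higher and 912 lower than input, and in KO 653 and 936. The balance depends on the scaling: the higher bins made up 37.9% of 1701 calls in WT and 35.4% of 1512 in KO with the autosomal total, and 46.8% of 1761 and 51.1% of 1525 with DESeq2 size factors. Fewer bins were called in KO with the compared groups alone (917), without the Xray-named γH2AX (771), or without the NT-named (941) or Xray-named (715) input library. The bin 39000001 to 40000000 of chromosome 17, which holds the 18S ribosomal RNA copy Rn18s-rs5, had the largest excess, at 3.68 in WT (SE 0.407, adjusted p = 0.000954) and 4.40 in KO (SE 0.421, adjusted p = 0.000403). Its γH2AX libraries held 10100 and 4950 CPM in WT and 17200 and 7340 in KO, with the NT-named library the higher in both. Reads of ribosomal DNA repeats from elsewhere could be counted in this copy. The KO libraries exceeded the WT libraries of like name, but a test of the difference itself that ignores the names did not pass (0.72, SE 0.518, adjusted p = 0.937, range over alternatives 0.026 to 1). The lowest of that range came from the block by column name, under which the bin passed. The difference was -0.019 without the NT-named and 1.22 without the Xray-named γH2AX KO library, and 1.32 and 0.30 without the NT-named and Xray-named γH2AX WT library.

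High γH2AX against input was also found at 109000001 to 110000000 of chromosome 11 with Prkar1a (1.09 in WT, 1.56 in KO), 11000001 to 12000000 of chromosome 16 with Gspt1 and Snx29 (0.97 and 1.14), 5000001 to 6000000 of chromosome 3 with Zfhx4 (0.80 and 1.37), 146000001 to 147000000 of chromosome 5 with Cdk8 (0.80 and 1.16) and 57000001 to 58000000 of chromosome 16 with Col8a1 (0.72 and 0.97). The last bins of chromosomes 7 (145000001 to 145441459, 0.79 and 0.77) and 2 (182000001 to 182113224, 0.71 and 0.64) rose above input in both genotypes. The last bin of X (170000001 to 171000000, with Asmt) had 0.69 in WT and 0.60 in KO, although the X as a whole lay below input. In KO, 123000001 to 124000000 of chromosome 9 with Lars2 also rose above input, by 0.44 to 0.90 over alternatives (662 ± 139 against 415 ± 5.86 CPM, SD, n = 2 each). In WT γH2AX held 495 ± 71.7 CPM there against 320 ± 1.01 in input, so the excess was not particular to KO. The last bin of chromosome 8 rose above input in WT (0.81) with 0.026 in KO (adjusted p = 0.808), and the last bin of chromosome 13 in KO (1.03) with 0.24 in WT (adjusted p = 0.0593). The Zfhx4 bin lost its call in WT without the NT-named γH2AX library (0.50, adjusted p = 0.0754) or either input library (0.0542 and 0.0588), and the chromosome 13 bin passed in WT without the Xray-named γH2AX library (0.32, adjusted p = 0.0431). The lowest bin was 24000001 to 25000000 of chromosome 1 (-0.80 in WT, -0.97 in KO). In WT γH2AX held 289 ± 6.31 CPM there and H2AX 276 ± 3.83, against 505 ± 4.51 in input (SD, n = 2 each). Next came 22000001 to 23000000 of chromosome 2 with Gad2 (-0.38 and -0.49), 92000001 to 93000000 of chromosome 4 with Izumo3 (-0.38 and -0.38) and 16000001 to 17000000 of chromosome 10, where no protein-coding gene starts (-0.36 and -0.41). The other bins lowest in WT were 114000001 to 115000000 of chromosome 3 with Col11a1 (-0.35), 49000001 to 50000000 (Grik2, -0.34) and 48000001 to 49000000 of chromosome 10 (-0.33), 111000001 to 112000000 of chromosome 3 (-0.33), and 61000001 to 62000000 (-0.33) and 68000001 to 69000000 (-0.32) of chromosome 16. In KO they were 80000001 to 81000000 of chromosome 5 (-0.37), 94000001 to 95000000 of chromosome 7 (-0.37), 96000001 to 97000000 of chromosome 2 with Lrrc4c (-0.36), 27000001 to 28000000 of chromosome 13 with the prolactin family (Prl, -0.36), 15000001 to 16000000 of chromosome 10 (-0.35) and 86000001 to 87000000 of chromosome 16 (-0.35).

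Among the loci named in advance, γH2AX lay above input in the bins of Sirt7 (0.41 in WT, 0.31 in KO), Rnf8 (0.34 and 0.30), Mdc1 (0.31 and 0.23), H2ax (0.28 and 0.20) and Brca1 (0.27 and 0.20) in both genotypes, and of Trp53bp1 in WT (0.12, adjusted p = 0.0257). H2AX also held more than input in these bins in WT, though this was not tested. Mean CPM in WT were 546 in H2AX, 547 in γH2AX and 410 in input for Sirt7, and 537, 555 and 438 for Rnf8. For Mdc1 they were 574, 600 and 484, for H2ax 393, 399 and 328, and for Brca1 353, 372 and 309. In γH2AX the escape genes Kdm6a (-0.14 and -0.16) and Mid1 (-0.15 and -0.11) lay below input in both genotypes, and Prkdc in KO (-0.076, adjusted p = 0.0406). The Xist bin did not differ from input (0.024, adjusted p = 0.557, in WT and -0.010, adjusted p = 0.818, in KO), nor did the remaining loci of these lists. Several of the KO calls rest on single libraries. Over all alternatives Prkdc was called in KO only 2 times, against 11 for Sirt7. Without the Xray-named γH2AX KO library those of Mid1 (-0.072, adjusted p = 0.122), H2ax (0.12, adjusted p = 0.0964) and Prkdc (-0.072, adjusted p = 0.118) were lost. Without the NT-named or Xray-named input KO library H2ax (adjusted p = 0.0812 and 0.0982) and Prkdc (0.191 and 0.0797) were lost, Prkdc also without the NT-named γH2AX KO library (0.127), and Brca1 without the Xray-named input KO library (0.17, adjusted p = 0.0574). Trp53bp1 lost its WT call without the Xray-named γH2AX library (0.086, adjusted p = 0.115) or either input library (0.0584 and 0.111), and with the autosomal total as scaling (0.11).

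By list, 184 of 241 gene-rich bins were above input in WT and 23 below (209 adjusted over the list alone), with 154 and 25 in KO (182). Gene-poor bins showed the opposite, 4 above and 241 below of 287 in WT (249) and 5 and 225 in KO (236). Distal bins were above input in 64 of 95 cases and below in 14 in WT (78), and in 55 and 15 in KO (72). Of 10 bins with p53 targets such as Cdkn1a and Mdm2, 9 were above and 1 below in WT (10), and 7 and 1 in KO (8). Of 9 DNA damage response bins 6 were above and 0 below in WT (6), and 5 and 1 in KO (6). On the X, 12 bins were above input and 91 below in WT (101), and 16 and 67 in KO (79). Camera called these lists in WT, with adjusted p = 8.48e-13 for gene-rich, 2.49e-21 for gene-poor, 5.72e-08 for distal, 0.03 for p53 target, 0.0374 for DNA damage response and 4.36e-07 for X bins, and also X bins proximal (0.0203) and distal (5.57e-08) to Dxz4. With an estimated correlation the adjusted p was 0.297 for distal bins, 0.546 for the DNA damage response and 0.536 for the others. In KO 5 lists were called, gene-rich (4.93e-13), gene-poor (8.21e-16), distal (8.32e-08), p53 target (0.0259) and X bins distal to Dxz4 (0.00047), with adjusted p = 0.3 for distal bins and 0.746 for the others with an estimated correlation. Gene density also separated the 2 γH2AX libraries of each genotype. Against its Xray-named partner, the NT-named γH2AX library had a median log2 of -0.11 in bins with at least 20 protein-coding genes, in KO and WT alike, and of 0.14 (KO) and 0.12 (WT) in bins without any.

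As a whole the X lay below input in γH2AX, by -0.099 in WT (SE 0.00965, adjusted p = 0.000149) and by -0.047 in KO (SE 0.00965, adjusted p = 0.00871). The KO value lost its call without the Xray-named input KO library (-0.042, adjusted p = 0.0602, range over alternatives 0.00656 to 0.0602). X reads were also a smaller share of autosomal reads in H2AX than in input (4.83% and 5.11% in WT, 5.5% and 5.67% in KO). In γH2AX, chromosomes 17 (0.26 in WT, 0.43 in KO), 11 (0.11 and 0.097) and 19 (0.042 and 0.043) lay above input in both genotypes. The value of chromosome 17 includes the Rn18s-rs5 bin, which weighs heavily in it. Mean γH2AX there was 7530 CPM against 586 in input in WT, and 12300 against 580 in KO. No value of the chromosome without that bin is given here, so a chromosome-wide excess is not shown. Chromosomes 3 (-0.076 and -0.049), 10 (-0.040 and -0.050), 1 (-0.039 and -0.038) and 13 (-0.034 and -0.025) lay below it in both, chromosome 16 in WT (-0.021) and chromosome 2 in KO (-0.092).

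The clones were used to compare KO cells with the same cells carrying SIRT7-WT. The Sirt7 bin was again examined first. In γH2AX it held 534 and 399 CPM in KO clones, 1950 and 9630 in KO clones carrying SIRT7-WT, and 689 and 576 in HY clones. In H2AX the values were 746 and 932, 1100 and 1510, and 1150 and 1330 CPM. Reads of the SIRT7-WT sequence that some of these clones carry could be counted in this bin, which was not tested. A difference here therefore need not be a change of γH2AX on chromosome 11. The bin was the only one of 2582 that passed between KO clones with and without SIRT7-WT, and it rose by 3.63 in γH2AX (SE 0.512, adjusted p = 0.0141). With the replicate number as a block it did not pass (3.35, adjusted p = 0.29), so that 0 bins were called, and DESeq2 called 1. The call was also lost without KO clones replicate 1 (3.86, adjusted p = 0.059) or replicate 2 (3.35, adjusted p = 0.356), within 5.06e-09 to 0.948 over alternatives, and the change was 2.10 without replicate 2 of the clones carrying SIRT7-WT. At an unadjusted p under 0.05, 23 bins differed. All other bins of the X inactivation, escape and DNA damage response lists had an adjusted p of 0.99 to 0.996, the Xist bin with a log2 change of 0.043.

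**Figure D4:**
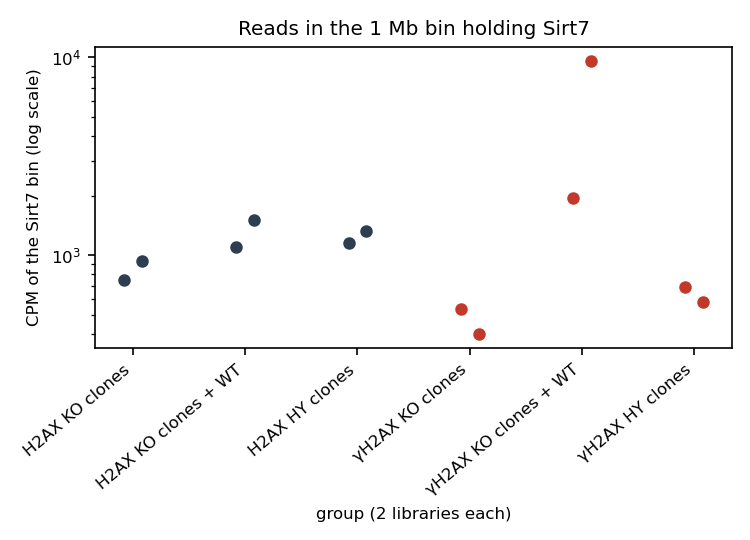
CPM (vertical axis, log scale) of the 1 Mb bin that holds Sirt7 in each clone library (points), with H2AX in blue and γH2AX in red for KO clones, KO clones carrying SIRT7-WT and HY clones. Both γH2AX libraries of clones carrying SIRT7-WT (1950 and 9630) lie above the other γH2AX libraries and differ widely from each other.

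H2AX differed between the same clones in 0 of 2582 bins by edgeR's quasi-likelihood test, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. The 3 smallest p-values, none passing, belonged to the Sirt7 bin (0.64, adjusted p = 1), 35000001 to 36000000 of chromosome 9 (-0.17) and 118000001 to 119000000 of chromosome 14 (0.11). Relative to H2AX, γH2AX changed in 0 bins by the same test, with 1 at an unadjusted p under 0.05 and 0 by DESeq2. The smallest p-values were those of the Sirt7 bin (3.00, SE 0.667, adjusted p = 1), the Rn18s-rs5 bin of chromosome 17 (0.72, adjusted p = 1) and the Gspt1 bin of chromosome 16 (0.27, adjusted p = 1). Without replicate 1 of the γH2AX clones carrying SIRT7-WT the Sirt7 bin passed relative to H2AX (3.73, adjusted p = 2.86e-06), and without replicate 2, the library with 9630 CPM, the change was 1.46 (adjusted p = 0.546), within 2.86e-06 to 1 over alternatives.

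The X did not differ detectably between KO clones with and without SIRT7-WT. X reads were 6.12% ± 0.35 of autosomal reads in γH2AX of KO clones and 5.72% ± 0.15 with SIRT7-WT (SD, n = 2 each), and 4.24% ± 0.1 and 4.15% ± 0.052 in H2AX. The log2 difference was -0.098 in γH2AX (SE 0.104, adjusted p = 0.999), -0.029 in H2AX (SE 0.104, adjusted p = 0.994) and -0.069 for γH2AX relative to H2AX (SE 0.147, adjusted p = 0.997). A change as large as that of the X between KO and WT cells (0.20) would be less than 2 of these standard errors, so the clones could hardly have shown it. Camera called 9 lists in γH2AX. Gene-rich bins were higher with SIRT7-WT (median 0.20, adjusted p = 1.54e-29, and adjusted p = 0.0916 with an estimated correlation), as were bins of the DNA damage response (0.24, adjusted p = 1.26e-06, 0.0916 with the estimate), of p53 targets (0.22, adjusted p = 0.000399, 0.333 with the estimate) and distal bins (0.084, adjusted p = 0.000277, 0.339 with the estimate). Gene-poor bins (-0.13, adjusted p = 1.06e-25, 0.333 with the estimate), long fragile-site genes (-0.091, adjusted p = 0.00324, 0.581 with the estimate) and all X bins (-0.079, adjusted p = 9.02e-08, 0.709 with the estimate) were lower. X bins on both sides of Dxz4 were lower too (0.718 proximal and 0.709 distal with the estimate). The single called member of the gene-rich, distal and DNA damage response lists was the Sirt7 bin (1 of 241, 1 of 95 and 1 of 9, and 1 adjusted over the list alone in each). In H2AX 9 lists were called, and the distal bins (adjusted p = 0.00148) lost the call with the replicate block (adjusted p = 0.0771). Relative to H2AX 8 lists were called, and fibroblast genes (adjusted p = 0.0898) passed with the block only (adjusted p = 0.0315). None of these calls held with an estimated correlation (adjusted p = 0.388 for distal bins, and 0.744 for fibroblast genes with the block). Within groups, too, libraries differed along gene density: relative to H2AX, the difference of replicate 1 and 2 had a Spearman rho with gene count of 0.698 in KO clones, 0.614 with SIRT7-WT and 0.657 in HY clones.

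HY clones differed from KO clones carrying SIRT7-WT mainly on chromosome 15. Chromosome 15 was lower in γH2AX of HY clones by -0.57 against KO clones carrying SIRT7-WT (SE 0.123, adjusted p = 0.00766) and by -0.55 against KO clones (SE 0.123, adjusted p = 0.0115). Relative to H2AX it differed by 0.019 and 0.027 (adjusted p = 0.999 and 0.998), so that H2AX was lower by a similar amount. Whether the clones differ in DNA content there was not tested, since their input columns were not used. Of the 46 lower bins, 44 lay on chromosome 15, and the other 2 were the Sirt7 bin (-3.19, adjusted p = 0.0231) and the Asmt bin at the end of X. The Sirt7 value may again include reads of the carried SIRT7-WT sequence. The lowest of chromosome 15 were 79000001 to 80000000 with Sox10 and Pdgfb (-0.84), 76000001 to 77000000 with Plec and Hsf1 (-0.84) and 102000001 to 103000000 with the Hoxc cluster (-0.81). In the Sox10 bin γH2AX held 488 ± 17.5 CPM in HY clones and 872 ± 25.4 in KO clones carrying SIRT7-WT, and H2AX 956 ± 211 and 1440 ± 25 (SD, n = 2 each). The 4 higher bins were neighbours on chromosome 12 (115000001 to 116000000, 0.87; 116000001 to 117000000, 0.54; 117000001 to 118000000 with Dnah11, 0.62; 118000001 to 119000000, 0.51). In H2AX, 115000001 to 116000000 likewise held 284 ± 22.3 CPM in HY clones and 156 ± 23 in KO clones carrying SIRT7-WT (SD, n = 2 each).

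The Asmt bin (X 170000001 to 171000000) was lower in HY clones than in KO clones carrying SIRT7-WT (-1.44, SE 0.172, adjusted p = 0.00224) and was the only bin of 2582 that passed against KO clones (-1.26, SE 0.172, adjusted p = 0.00945). Its H2AX libraries held 47.4 and 52.6 CPM in HY clones, 126 and 156 in KO clones and 156 and 156 with SIRT7-WT. Without γH2AX HY clones replicate 1 both calls were lost (-1.46, adjusted p = 0.127, and -1.30, adjusted p = 0.294), and that against KO clones without KO clones replicate 1 (-1.01, adjusted p = 0.0691). Against clones carrying SIRT7-WT the 50 calls became 1 without HY replicate 1, 84 without HY replicate 2, and 3 or 2 without replicate 1 or 2 of the clones carrying SIRT7-WT. In the first case the adjusted p was 0.225 for the Sirt7 bin, for the named bins of chromosome 15 and for the 4 bins of chromosome 12 (range over alternatives of the Sox10 bin 0.000248 to 0.225). Without HY replicate 2 the calls of Sirt7 (0.0641), Sox10 (0.0577), Plec (0.0624) and, on chromosome 12, 116000001 to 117000000 (0.0624) and 118000001 to 119000000 (0.0568) were lost. Without replicate 1 of the clones carrying SIRT7-WT the named chromosome 15 bins had an adjusted p of 0.0741 and those of chromosome 12 of 0.0741 to 0.192, and without its replicate 2 of 0.177 to 0.189 and of 0.189 to 0.658. Against KO clones the count was 66 without HY replicate 2 and 0 without KO clones replicate 1. DESeq2 called 112 and 135 bins, and 221 and 273 had an unadjusted p under 0.05.

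The X as a whole differed by -0.020 between HY clones and KO clones carrying SIRT7-WT (SE 0.104, adjusted p = 0.858) and by -0.12 against KO clones (SE 0.104, adjusted p = 0.546), with X shares in HY clones of 5.64% ± 0.78 in γH2AX and 4.02% ± 0.25 in H2AX (SD, n = 2 each). Without γH2AX HY clones replicate 1 the differences were 0.12 and 0.017, and the first was 0.0069 without replicate 2 of the clones carrying SIRT7-WT. Besides the Sirt7 bin against clones carrying SIRT7-WT, no bin of the X inactivation, escape or DNA damage response lists passed (lowest adjusted p 0.581 and 0.256). Camera called 4 and 7 lists, among them gene-rich bins (median -0.068, adjusted p = 0.00946, against clones carrying SIRT7-WT, and 0.10, adjusted p = 0.00119, against KO clones), with 10 of 241 lower in the former (11 adjusted over the list alone). None of them held: with an estimated correlation the adjusted p was 0.907 for each list against clones carrying SIRT7-WT, and 0.748 or, for gene-poor bins, 0.76 against KO clones. Relative to H2AX, a comparison that was added, HY clones differed in 0 bins from either group by edgeR's quasi-likelihood test and 0 by DESeq2, with 6 and 5 bins at an unadjusted p under 0.05. The smallest p-values, none passing, were those of the Sirt7 bin (-3.12, adjusted p = 0.93), 129000001 to 129401213 of chromosome 8 (1.34) and 149000001 to 149736546 of chromosome 6 (0.62) against clones carrying SIRT7-WT. Against KO clones they were those of the chromosome 6 bin (0.76), the chromosome 8 bin (1.35) and the last bin of chromosome 5, 151000001 to 151834684 (0.98). Without HY replicate 2 the chromosome 8 bin passed in both (1.98, adjusted p = 0.00125 and 0.00123) and that of chromosome 5 against KO clones (1.45, adjusted p = 0.0465). Without HY replicate 1 the chromosome 8 changes were 0.19 and 0.19 and that of chromosome 5 was 0.26, so these calls rest on that library, which held 390 CPM on chromosome 8 and 804 on chromosome 5 (350 in replicate 2). The Sirt7 bin passed without replicate 1 of the clones carrying SIRT7-WT (-3.86, adjusted p = 1.74e-06) or with the compared groups alone (-3.12, adjusted p = 0.0212), and not without their replicate 2 (-1.59, adjusted p = 0.237). Camera called 4 and 5 lists, the DNA damage response (median -0.17, adjusted p = 3.87e-09, and adjusted p = 0.059 with an estimated correlation) and gene-rich bins (-0.12, adjusted p = 1.86e-35, 0.0596 with the estimate) among those against clones carrying SIRT7-WT, and none of them held (0.709 or more with the estimate against KO clones). Both of these lists hold the Sirt7 bin (-3.12 here), and neither was tested without it.

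Finally, the effect of losing SIRT7 was compared between the 2 tables, which share no library in these comparisons. Over 2582 bins the γH2AX change of KO against WT cells and that of KO clones against the same clones carrying SIRT7-WT had r = 0.0786 (circular shift permutation p = 0.103) and rho = 0.0775 (permutation p = 0.135). On autosomes r was 0.039 (permutation p = 0.354). The KO against WT change followed that of input (r = 0.96), and the clones with and without SIRT7-WT are the same cell lines. A low r was therefore likely whatever the effect of SIRT7, and says little about it. Taken relative to H2AX in both tables, the changes correlated with r = 0.254 and rho = 0.557, each with a permutation p of 0.001, the smallest that 1000 shifts can give. Differences between libraries of a group, alike in labelled SIRT7 status, had larger absolute rho between the tables. It was -0.74 for KO clones, -0.80 with SIRT7-WT and -0.66 for HY clones. The 2 libraries with SIRT7-WT differed in the Sirt7 bin (1950 and 9630 CPM in γH2AX), so their difference may involve the amount of SIRT7, which these reads do not measure. After adjustment for gene count and the NT-named against Xray-named difference the partial rho was 0.172 (permutation p = 0.001). Bins are not independent replicates, and 4 such relations were computed.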

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

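All tests of the first and second pattern below were chosen only after results were seen, and that of γH2AX placement was later held to the fit with a block by column name as well. Those of the third were written down before they were run, but after the agreement relative to H2AX and its relation to gene count had been seen. The following results stood out because the KO against WT difference itself differed between assays by a test of that difference. Relative to H2AX these were 128000001 to 129000000 (-0.486) and 129000001 to 129401213 (-0.955) of chromosome 8, 121000001 to 122000000 of chromosome 11 (-0.322) and 120000001 to 120421639 of chromosome 13 (1.00), and relative to input the same bin of chromosome 11 (-0.317). All 4 bins are among the last 2 of a chromosome, as are 40 of 2582 tested bins. The called bins held at least 15967 reads, and the smallest absolute change relative to input was 0.317. This chromosome-end pattern was weighed first, with tests written after it was seen. It was replaced by the third pattern below after those values were known, and no explanation of it is offered. Its probabilities are not given, since they were computed on the bins in which the pattern was noticed.

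The first pattern is the KO against WT difference of γH2AX over many bins. Copy number differences between the lines predict that input differs alike. The changes of γH2AX and input had r = 0.96 with a slope of 0.965, and 28.2% of the SD was left relative to input, so differences in DNA content could account for most of the pattern. The pattern did not turn over with library size: KO had 0.775 times the reads of WT in γH2AX and 1.08 times in H2AX while the changes kept r = 0.952. The changes were scaled for library size before this test, which limits what it can exclude. Whether γH2AX placement also changed with unchanged DNA content cannot be told: 1 bin stayed called relative to input, but 352 passed with a replicate block by column name, and H2AX relative to input had 277 under that block.

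The second pattern is that NT-named and Xray-named γH2AX libraries differ alike in KO and WT (r = 0.959 over bins). Library size is excluded, as the read ratio of NT-named to Xray-named was 0.98 in KO and 0.986 in WT. A few extreme bins are excluded, since r was 0.96 without the 12 bins highest against input. A real difference in irradiation and a shared preparation batch cannot be told apart, because the input libraries also shared some of their difference (r = 0.486). Against input, the Xray-named libraries had the larger spread in γH2AX (SD 0.192 in KO and 0.214 in WT, against 0.121 and 0.136) and in H2AX (0.155 and 0.181, against 0.142 and 0.144).

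The third pattern is that γH2AX relative to H2AX differed alike for loss of SIRT7 in both tables (rho = 0.557). A shared axis of gene density fits, because differences between libraries alike in labelled SIRT7 status had a median absolute rho of 0.74 between the tables (-0.74, -0.80 and -0.66 for KO clones, KO clones carrying SIRT7-WT and HY clones). The difference within clones carrying SIRT7-WT may involve the amount of SIRT7. Both changes also followed the NT-named against Xray-named difference (rho = 0.592 and 0.82). Loss of SIRT7 beyond that axis cannot be told: after adjustment for gene count and that difference the partial rho was 0.172 (circular shift permutation p = 0.001, the smallest that 1000 shifts can give), between the limits set for either verdict.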

How the results depend on the processing

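Of 386 alternatives for counts and chromosome values 312 gave a like result and 74 did not. A count of called bins or lists was taken as alike within a factor of 1.5 of the main count. A chromosome value was alike with the same sign and call. Of 2012 alternatives for single bins 1780 gave the same call and 232 did not (126 weaker, 51 stronger, 33 moved, 22 reversed). The X stayed above threshold and higher in KO in γH2AX, H2AX and input under all alternatives, except against input (γH2AX 0.0518, H2AX 0.0392). Where a library was left out, the remaining one of its group was assumed to vary like the other groups. For all values below the cause was not tested, except where fewer samples were fitted.

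Against input, γH2AX calls between KO and WT fell to 1 and H2AX calls to 0. Bins that passed before and turned in sign, none of them called, were in γH2AX those of Asmt (-0.0966), Erbb2 (-0.0695), Sdk2 (-0.000749), Tbx21 (-0.0808), Hoxb (-0.0598), the Vmn1r genes of chromosome 7 (0.0294, 0.0201, 0.0152), Mup (0.0184), Scgb1b10 (5.29e-05), Xist (-0.0343), Firre (-0.00852), Dxz4 (-0.0283), Kdm6a (-0.0206), Ddx3x (-0.0266), Eif2s3x (-0.0666), Pbdc1 (-0.0464), Rnf168 (-0.0377), Brca1 (-0.0736) and Prkdc (-0.028), and in H2AX those of Asmt (-0.164) and Erbb2 (-0.0372).

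With the compared groups alone, calls became 919 in γH2AX KO against WT, 0 relative to H2AX, 0 relative to input, 45 for H2AX relative to input, 917 for γH2AX against input in KO, 0 for KO clones with against without SIRT7-WT, 0 for HY against KO clones and 1 for HY against KO clones carrying SIRT7-WT relative to H2AX. DESeq2 called 16 bins relative to H2AX, 6 relative to input, 12 for H2AX relative to input, and 112 and 135 for HY against KO clones with and without SIRT7-WT. DESeq2 size factors gave 3 for HY against KO clones carrying SIRT7-WT. Without bins of unusual input the counts were 2 relative to H2AX, 0 for KO clones with against without SIRT7-WT and 2 for HY against KO clones carrying SIRT7-WT. The autosomal total gave 4 relative to input, and the X of HY against KO clones carrying SIRT7-WT relative to H2AX was -0.016 with TMM factors.

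NT-named γH2AX libraries alone gave 27 bins relative to H2AX, 44 relative to input and 0.0639 for the X relative to input, and Xray-named ones 22, 10 and 0.0398, with 1 γH2AX library per genotype and so no replicate check. No paired analysis was possible because the first table's columns carry no replicate numbers, other than a fit that pairs libraries by column name. This replicate block by column name, chosen after the data were seen (r of deviations 0.959 in γH2AX, 0.68 in H2AX and 0.486 in input), gave 2, 352 and 277 bins relative to H2AX, relative to input and for H2AX relative to input, and called the Rn18s-rs5 bin relative to input (0.683, adjusted p = 0.026). Relative to H2AX the last bins of chromosomes 13 (adjusted p = 0.0762) and 8 (0.0689 and, for the bin before it, 0.0621) had no call under it, and that of chromosome 11 had (0.0325). The replicate block of the clones gave 0 for KO clones with against without SIRT7-WT and changed no other call of KO clones with against without SIRT7-WT but those given above. For HY against KO clones relative to H2AX, a block by cell line family added list calls of fibroblast genes (adjusted p = 0.029), ribosomal DNA chromosomes (0.0106) and olfactory receptor bins (0.0333), each with adjusted p = 0.724 with an estimated correlation. The block by column name moved list calls of the DNA damage response (0.0179 relative to H2AX, 0.013 relative to input), fibroblast genes (0.0382 relative to H2AX) and, for γH2AX against input in WT, long fragile-site genes (0.048) and X bins proximal to Dxz4 (0.0501). With an estimated correlation under that block the adjusted p was 0.827 for the lists relative to H2AX, 0.3 relative to input, and 0.534 and 0.718 in WT. The planned comparison of parental genomes between KO and WT was not run. Its columns matched groups only, as did the total columns compared here, so the match alone does not preclude it.

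Leaving out each library gave ranges of 0 to 5 bins relative to H2AX, 0 to 4 relative to input, 715 to 1856 for γH2AX against input in KO, 0 to 1 for KO clones with against without SIRT7-WT, 1 to 84 and 0 to 66 for HY against KO clones with and without SIRT7-WT, and, relative to H2AX, 0 to 1, 0 to 2 and 0 to 3 for the same 3 comparisons. For the X the ranges were 0.0411 to 0.0626 relative to input, -0.0517 to -0.0415 for γH2AX against input in KO, -0.17 to 0.115 and -0.267 to 0.0172 for HY against KO clones with and without SIRT7-WT, and -0.123 to 0.161 and -0.192 to 0.0923 for the same relative to H2AX. The parental ratio of γH2AX against H2AX in WT ranged from -0.0157 to 0.00133. All X bins of HY against KO clones carrying SIRT7-WT lost their list call with the autosomal total (adjusted p = 0.0749). Of 209 list tests of the 11 planned comparisons 69 were called at the preset correlation and 3 with an estimated one, and the 4 added comparisons had 7, 4, 4 and 5 calls and 0 with an estimate. The agreement of the tables relative to H2AX was 0.254.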

Other observations

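Reads assigned to parental genomes were used for WT cells only, in an analysis added after the data were seen. In WT the X chromosome held fewer reads of genome1 than of genome2. Genome1 made up 34.46% of assigned X reads in γH2AX of replicate 1 (34.39 to 34.52) and 34.23% of replicate 2 (34.19 to 34.28), 34.59% (34.52 to 34.67) and 34.33% (34.27 to 34.38) in H2AX, and 33.53% (33.47 to 33.58) and 33.42% (33.38 to 33.47) in input. These are exact 95% intervals that cover counting error only. On autosomes together the share was 53.96% to 54.22%. Log2 ratios of genome1 to genome2 were tested per chromosome and per bin with limma's moderated t test. Adjustment was over the chromosomes or bins of a comparison. The ratio of the X was higher in γH2AX than in input by 0.056 on the log2 scale (limma, SE 0.00792, adjusted p = 0.00237). In H2AX it was higher than in input by 0.063 (limma, adjusted p = 0.00103). Between γH2AX and H2AX it differed by -0.0072 (limma, adjusted p = 0.522), and by 0.0013 without H2AX WT replicate 1. Autosomes passed as well, lower in γH2AX than in input on chromosomes 11 (-0.043, adjusted p = 0.00412 by limma) and 10 (-0.027, adjusted p = 0.0158 by limma). Between γH2AX and H2AX chromosomes 2 (-0.027), 8 (0.028), 9 (-0.022) and 11 (-0.027) passed. Of 164 X bins 124 had a higher ratio in γH2AX than in input, of which 2 passed. In H2AX against input 27 X bins passed, all higher, and in γH2AX against H2AX 2, both lower.

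Parental shares also varied between autosomes in input of WT replicates 1 and 2. Genome1 made up 29.48% and 29.45% on chromosome 16 and 31.7% and 31.53% on chromosome 1, but 67.96% and 68.03% on chromosome 3, 67.04% and 67.16% on chromosome 6, and 63.93% and 63.74% on chromosome 18. On chromosome 5 it was 50.01% and 50.1%.

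Mitochondrial reads made up 0.218% of input in KO and 0.165% in WT, 0.023% and 0.0142% in γH2AX, and 0.00095% and 0.000677% in H2AX (means, n = 2 each).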
